A study of Homo sapiens with 9 samples.

How the data were processed

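Polyadenylated RNA was sequenced from 9 libraries of LF1 cells, a strain of normal human lung fibroblasts. The labels give 3 control shRNA libraries with no day, 3 libraries taken 4 days after infection with an shRNA against EZH2, and 3 taken 8 days after it. Because the controls carry no day, time in culture is not separated from the knockdown in any comparison with control. Between day 4 and day 8 the shared controls cancel, so time in culture is not separated from time after infection either. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

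Per the submitters' processing notes, paired-end reads were trimmed with Trim Galore 0.4.0, aligned to hg19 with HISAT2 2.1.0 and assigned to genes with featureCounts, and FPKM values and differential expression were obtained with DESeq2 1.12.4. The authors deposited 1 table of FPKM (fragments per kilobase of gene model, scaled by sequencing depth) for 29699 genes, with a column for each library. The annotation release, the strand setting and the treatment of multiply mapped reads are not given in the sources used here. Values of overlapping genes, antisense pairs and near-identical copies (histone clusters, actins, CXCL chemokines, pseudogenes) are therefore uncertain.

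The FPKM values kept the trace of whole reads. For 25848 of the 25855 genes above 0 in at least 2 libraries (99.97%), all values were whole multiples of 1 read's worth. The tolerance was 0.05. Scrambled values gave a match for 0 of 300 genes. Those 300 were above 1 FPKM in every library and were searched less far than real genes missed at first. Genes above 0 in only a few libraries can match by arithmetic alone, so the shares are not a like-for-like comparison. Another 3844 genes were above 0 in only 1 library and could not be resolved. The per-library scale so recovered differed from median-ratio size factors by at most 0.0142%, and from library totals by up to 13.1%, so the deposited values carry a size-factor scaling. Recovered totals ran from 21431346 to 30563939 reads or read pairs per library. On 2000 simulated genes the recovery found whole reads for 2000, and 99.6% of these equalled the simulated reads.

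Tests were run on log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, with a variance trend in the empirical Bayes step. All 9 libraries entered a single fit with 6 residual degrees of freedom. Genes with an FPKM of at least 1 in at least 3 libraries were tested (11942 genes), and a Benjamini-Hochberg adjusted p under 0.05, two-sided, was called. Deviations from the group means correlated above 0.1 in 3 of 3 pairs of control and day 4 libraries with the same replicate number (0.128 to 0.44). The same held for 0 of 3 pairs of control and day 8 and 1 of 3 pairs of day 4 and day 8. Control replicate 2 correlated more with day 4 replicate 1 (0.144) than with its own number (0.128). Control and day 4 replicates 1 (Spearman -0.437 and -0.671) and 3 (0.652 and 0.727) also shared the sign of their correlation with GC content. Whether the numbers pair control with day 4 is therefore not settled, and the labels do not say what a number marks. The count test of the submitters could not be the main test on FPKM values. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. EZH2 was also compared by an exact two-sided permutation test of 3 against 3 libraries, whose smallest possible p is 0.1.

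Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of each comparison, and again with an estimated correlation and with fry. There were 29 lists of pathways, complexes and cell type markers. Members called over all genes are counted beside members called when p-values were adjusted over the list alone. Where leaving out 1 library or correcting for GC content moved a count of members by over 1.5 times and by more than 1 member, the moved count is given. The design, the lists, most alternatives and the rule for named genes were set before the data were examined. That rule takes EZH2, CDKN1A, CDKN2A, CDKN2B, LMNB1 and IL6 in both comparisons with control, where it adds the 8 largest rises and the 8 largest falls among called genes whose libraries do not overlap, with a mean FPKM of at least 2 in the higher group, and up to 3 called members of each list. Between the times it takes the 5 largest rises and the 5 largest falls, and up to 2 called members of each list. A few list members that the rule picks are not reported here one by one, though they stay in the list counts and tests. XIST, genes of the Y chromosome and symbols beginning with LOC, LINC, MIR, SNOR or ENSG were left out of the ranking by size.

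Coordinates, exon overlaps, GC content and length came from a GENCODE annotation of GRCh37, the assembly of hg19, matched by gene identifier for 28618 of the 29699 genes. GC content was available for 11720 of the genes tested; for a test of histone genes, missing values were filled through older symbols. The procedure was tested on simulated reads for 11935 genes with 68, 66 and 66 of them changed 1.5-fold, 2-fold and 4-fold. At day 4 against control it called 29.4% of the 1.5-fold, 59.1% of the 2-fold and 95.5% of the 4-fold changes. The shares were 33.8%, 68.2% and 90.9% at day 8 against control, and 29.4%, 54.5% and 90.9% between the times. False calls made up 8.27%, 4.48% and 5.69% of the calls in these simulations. The simulations called 133, 134 and 123 genes, against 6172, 6318 and 3815 in the data. Their adjusted threshold was therefore stricter, and these shares need not hold for the data.

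Alternatives covered the pseudocount, the filter, the scaling (rescaled to equal sums, median ratio, quantile), the variance trend, library weights, a fit of only the groups compared, a replicate block, a minimum fold change, a stricter threshold and each library left out in turn. A correction for GC content, with and without gene length or day 8 replicate 3, voom on the recovered reads, and a replicate block in a fit of control and day 4 alone were added after seeing the data. Figures and tables were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.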

Results

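Transcript levels were measured by RNA sequencing in 9 libraries of LF1 human lung fibroblasts, 3 from cells with a control shRNA and 3 each from cells taken 4 and 8 days after infection with a lentiviral shRNA against EZH2. EZH2 is the histone methyltransferase of the Polycomb repressive complex PRC2, which places the H3K27me3 mark of silenced genes. Reads recovered from the deposited FPKM values came to 30563939, 26088477 and 24574121 in control replicates 1 to 3. They came to 23725868, 21431346 and 25040325 at day 4, and to 26533685, 26694985 and 26343204 at day 8. The first principal component took 64.8% of the variance and ordered the groups as control, day 4, day 8. The second took 23.3%. On it, day 8 replicates 1 and 2 lay at 29.2 and 42.6, the day 4 libraries between -37.9 and -20.9, and day 8 replicate 3 at -8.54. Across genes, day 8 replicate 3 correlated with the other day 8 libraries at r = 0.969 and 0.951, and those with each other at 0.993; it correlated with the day 4 libraries at 0.952, 0.948 and 0.951. Deviations of single libraries from their group mean followed GC content across genes, with Spearman correlations from -0.671 to 0.727. Genes are not independent replicates in such correlations.

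**Figure D1:**
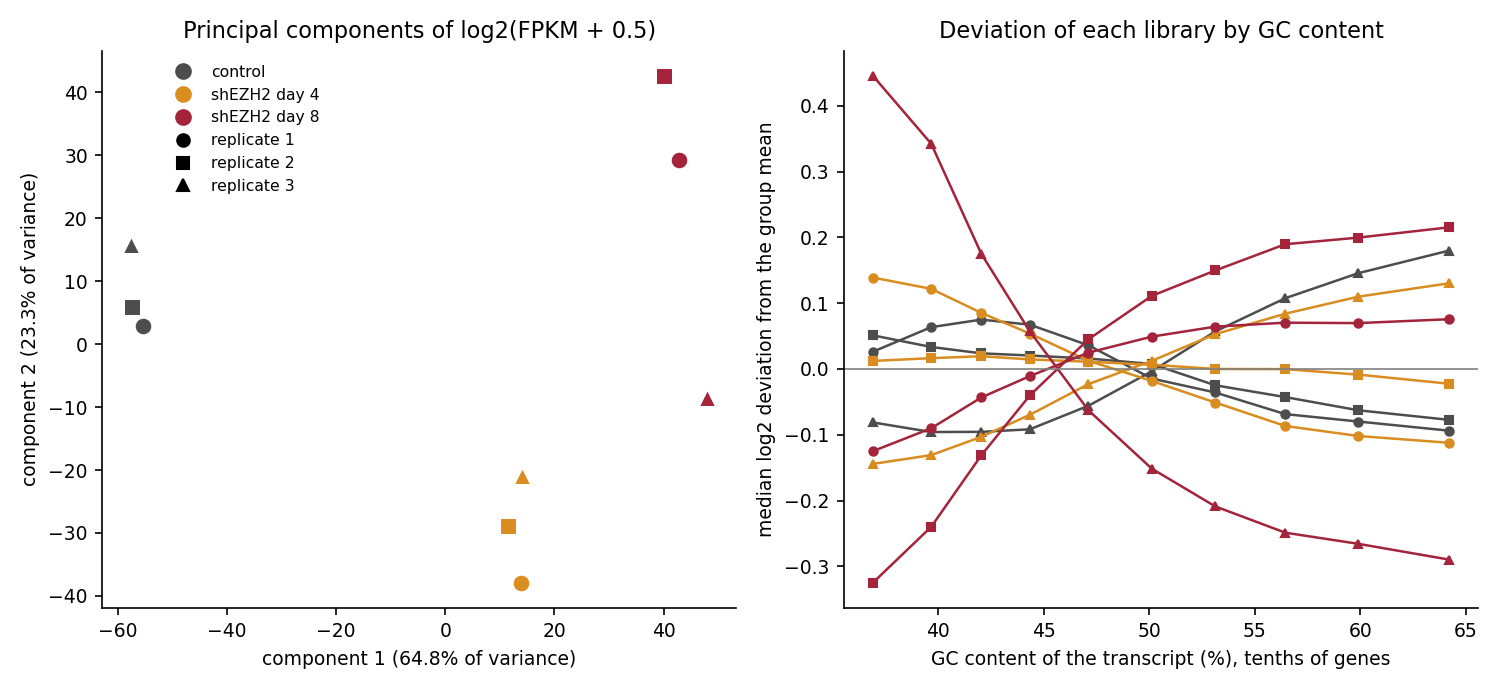
Left, scores of the 9 libraries on the first 2 principal components of log2(FPKM + 0.5), which took 64.8% and 23.3% of the variance. Right, median log2 deviation of each library from its group mean over deciles of genes ordered by GC content. Day 8 replicate 3 (Spearman correlation with GC content -0.657) and day 8 replicate 2 (0.656) bend in opposite directions. Because deviations are taken from the mean of the same libraries, a bend in 1 library forces an opposite bend among the others.

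The targeted gene was low in every knockdown library. EZH2 (ENSG00000106462.6, hg19 chromosome 7, 148504349 to 148581413, minus strand) had an FPKM of 7.99, 8.09 and 7.69 in the control libraries, 0.646, 0.551 and 0.60 at day 4, and 0.159, 0.133 and 0.225 at day 8. These values rest on 777 to 1063 recovered reads per control library, 61 to 80 at day 4 and 16 to 31 at day 8. The mean fell from 7.93 ± 0.212 in control to 0.599 ± 0.0478 at day 4 and 0.172 ± 0.0473 at day 8 (SD, n = 3 each), which is 7.56% and 2.17% of control. The log2 change was -2.94 at day 4 (SE 0.10, limma adjusted p = 2.1e-07) and -3.65 at day 8 (SE 0.10, adjusted p = 5.8e-09). Between the times it fell by 0.71 (adjusted p = 0.00077), a call lost under quantile normalization (-0.24, adjusted p = 0.076). The exact permutation p was 0.1 in each comparison, the smallest that 3 against 3 libraries allow. The other genes followed in every comparison lie, in hg19, on chromosome 6 from 36644237 to 36655114 on the plus strand (CDKN1A, ENSG00000124762.9), on chromosome 9 from 21967751 to 21995300 on the minus strand (CDKN2A, ENSG00000147889.12) and from 22002902 to 22009304 on the minus strand (CDKN2B, ENSG00000147883.9). LMNB1 (ENSG00000113368.7) lies on chromosome 5 from 126112315 to 126172712 on the plus strand, and IL6 (ENSG00000136244.7) on chromosome 7 from 22765503 to 22771621 on the plus strand.

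**Figure D2:**
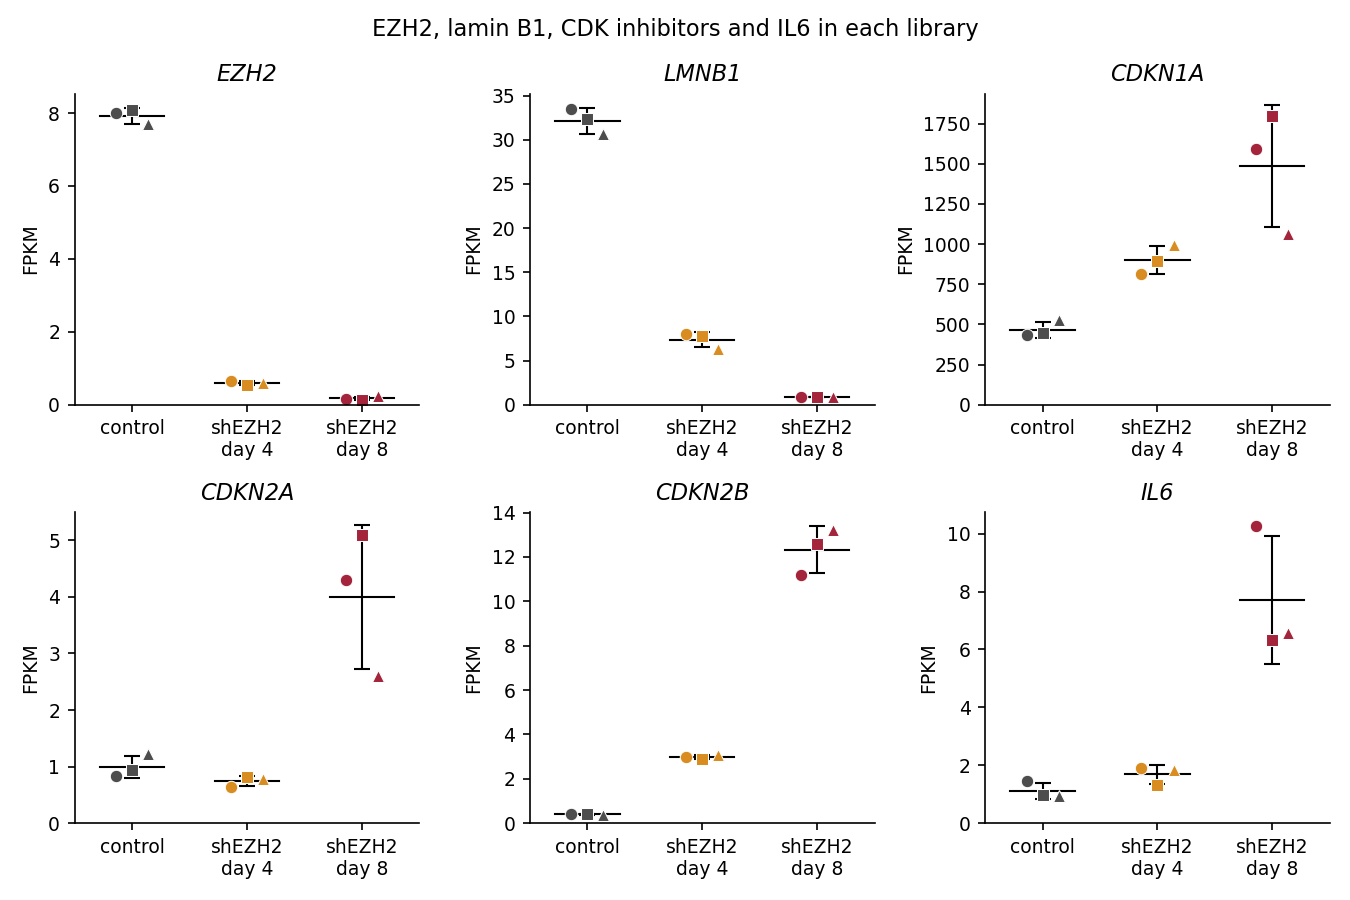
FPKM of EZH2, LMNB1, CDKN1A, CDKN2A, CDKN2B and IL6 in each library (points), with the group mean and SD (bars, n = 3 per group). EZH2 lay at 7.69 or more in the control libraries and at 0.646 or less in every knockdown library.

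The comparison of day 4 with control asks which transcripts differed early after infection with the EZH2 shRNA. The controls carry no day, so the differences at both times hold any effect of time in culture as well as that of the knockdown. At day 4, 48 of 51 DNA replication and S phase genes and 11 of 13 smooth muscle and myofibroblast markers had fallen, and 24 of 39 p53 targets had risen (list adjusted p = 2.1e-22, 1.1e-06 and 5.6e-06). With an estimated correlation none of these lists passed (adjusted p = 0.0905, 0.166 and 0.0905). The replicative helicase subunit MCM6 fell from an FPKM of 24.8 ± 1.05 to 2.68 ± 0.437, and smooth muscle actin ACTA2 from 267 ± 20.7 to 29.9 ± 2.01 (SD, n = 3). The chemokine gene IL8 (CXCL8) rose from 1.36 ± 0.0641 to 43.3 ± 8.53 and the neuropeptide precursor VGF from 0.820 ± 0.167 to 62.1 ± 4.53. LMNB1, which encodes lamin B1 of the nuclear lamina, fell from 32.1 ± 1.46 to 7.37 ± 0.893.

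Of 51 tested genes of DNA replication and S phase, 48 fell and 0 rose (48 and 0 adjusted over the list alone), with a median log2 change of -1.72. Thymidine kinase TK1 fell by 2.88 (SE 0.21) and the maintenance methylation factor UHRF1 by 2.84 (SE 0.08). The list passed camera at an adjusted p of 2.1e-22, with adjusted p = 0.0905 with an estimated correlation. Of 66 G2 and mitosis genes, 56 fell and 0 rose (56 and 0 adjusted over the list alone), among them CDC20, the activator of the anaphase-promoting complex, at -2.49 (SE 0.13), and the centromere gene CENPM at -2.33 (SE 0.17). That list's adjusted p was 1.9e-17, and adjusted p = 0.245 with an estimated correlation. Homologous recombination and Fanconi anaemia genes fell in 19 of 26 and rose in 2 (19 and 2 adjusted over the list alone); the list's adjusted p was 1.6e-05, and adjusted p = 0.245 with an estimated correlation. The rises numbered 0 without control replicate 2 or 3 or day 4 replicate 1 or 2. Among nuclear lamina and HMG protein genes, 9 of 12 fell and 1 rose (9 and 1 adjusted over the list alone), with LMNB2 at -2.18 (SE 0.13), LMNB1 at -2.06 (SE 0.10) and TMPO at -1.62 (SE 0.11). Here the adjusted p was 0.0019, and adjusted p = 0.166 with an estimated correlation.

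CDK inhibitors moved in both directions at day 4. CDKN2B, which encodes the CDK4 and CDK6 inhibitor p15, rose from 0.394 ± 0.0180 to 2.98 ± 0.0934 FPKM, a log2 change of 1.96 (SE 0.10, adjusted p = 7.4e-07). CDKN1A, which encodes p21, rose from 468 ± 49.6 to 902 ± 88.7 (0.95, SE 0.20, adjusted p = 0.0031). CDKN2A, the gene of p16 and ARF, had an FPKM of 0.996 ± 0.20 in control and 0.747 ± 0.0864 at day 4 (-0.26, adjusted p = 0.32), and its exons overlap those of CDKN2B-AS1. CDKN2C fell by 1.67 and CDKN3 by 0.99 on the log2 scale. In all, 4 of the 8 inhibitors rose and 2 fell (4 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.69). The rises numbered 2 without control replicate 1 or 2 or day 4 replicate 1 or 3.

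Targets of p53 rose in 24 of 39 tested genes and fell in 3 (24 and 3 adjusted over the list alone), with the stress cytokine GDF15 at 2.45 (SE 0.18), the ribonucleotide reductase subunit RRM2B at 2.38 (SE 0.36) and TP53INP1 at 2.16 (SE 0.20). The list passed camera (adjusted p = 5.6e-06), with adjusted p = 0.0905 with an estimated correlation. After the GC correction 28 rose and 6 fell. Cytokines and chemokines of the senescence-associated secretory phenotype rose in 11 of 18 and fell in 2 (11 and 2 adjusted over the list alone): CXCL1 rose by 3.76 (SE 0.20), while CXCL12 fell by 1.91 (SE 0.11). This list's adjusted p was 0.00069, and adjusted p = 0.445 with an estimated correlation. IL6 had an FPKM of 1.116 ± 0.283 in control and 1.69 ± 0.326 at day 4 (0.44, adjusted p = 0.098); after a GC correction it was called (0.57, adjusted p = 0.028), as it was with replicates paired (0.44, adjusted p = 0.0086), in a fit of the compared groups (adjusted p = 0.027), with library weights or equal sums (0.037 each) and with the replicate block (0.035). Its exons overlap STEAP1B. Secreted proteases and growth factors rose in 21 of 36 and fell in 9 (21 and 10 adjusted over the list alone), with the EGF receptor ligands AREG at 3.52 (SE 0.13) and EREG at 3.31 (SE 0.20) and hepatocyte growth factor HGF at 3.35 (SE 0.32). Their adjusted p was 0.0035, and adjusted p = 0.275 with an estimated correlation; without control replicate 2 the falls numbered 5. Lysosomal genes rose in 20 of 29 and fell in 1 (20 and 2 adjusted over the list alone), with cathepsin S (CTSS) at 1.39 (SE 0.14) and the peptidase TPP1 at 1.30 (SE 0.11); the adjusted p was 2.5e-05, and adjusted p = 0.275 with an estimated correlation. Lysosomal falls numbered 3 without day 8 replicate 3.

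Markers of smooth muscle and myofibroblasts fell in 11 of 13 and rose in 0 (11 and 0 adjusted over the list alone), led by ACTA2 at -3.14 (SE 0.15), ACTG2 at -3.06 (SE 0.14) and LMOD1 at -3.01 (SE 0.10). For these markers the adjusted p was 1.1e-06, and adjusted p = 0.166 with an estimated correlation. ACTA2 shares exons with ACTA2-AS1 and FAS, and actin genes are near-identical copies of each other. Fibroblast extracellular matrix genes split evenly, with 14 of 42 up and 14 down (14 and 16 adjusted over the list alone, list adjusted p = 0.85); periostin (POSTN) rose by 2.73 (SE 0.31), LAMB1 by 2.34 (SE 0.18) and COL11A1 by 2.03 (SE 0.20). Of 26 tested developmental regulators that carry H3K27me3 in many cell types, 6 rose and 15 fell (6 and 15 adjusted over the list alone, list adjusted p = 0.23), with FOXE1 at -2.60, TBX4 at -1.48 and SALL1 at 1.53. In this list 71 genes stayed below the expression filter, so the counts cover only members expressed in some of these libraries. H3K27me3 was not measured, so the members that carry the mark in these cells are not known. HOX genes rose in 4 of 14 and fell in 2 (4 and 2 adjusted over the list alone, list adjusted p = 0.59), with HOXB7 at -0.59; HOX rises numbered 2 without control replicate 1 or day 4 replicate 3.

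Among PRC2 subunits 3 of 11 rose and 3 fell (3 and 4 adjusted over the list alone, list adjusted p = 0.86): beside EZH2, PHF19 fell by 1.11 and MTF2 rose by 1.10. PRC1 subunits rose in 3 of 18 and fell in 5 (3 and 5 adjusted over the list alone, list adjusted p = 0.86), with CBX2 at -1.60; the rises numbered 5 without day 8 replicate 3, and 5 of 20 rose and 3 fell when libraries were rescaled to equal sums. Cholesterol biosynthesis genes rose in 2 of 23 and fell in 9 (2 and 9 adjusted over the list alone, list adjusted p = 0.45). Those that fell numbered 3 without day 4 replicate 1, 5 without day 4 replicate 2 and 4 without control replicate 3, and those that rose 5 without day 8 replicate 3. For NF-kappaB pathway genes 5 of 20 rose and 3 fell (5 and 3 adjusted over the list alone, list adjusted p = 0.20). Transcripts of the mitochondrial genome rose in 8 of 13 and fell in 0 (9 and 0 adjusted over the list alone), with MT-ND6 at 0.70. Their adjusted p was 0.0049, or 0.06 once GC content and length were both corrected, and adjusted p = 0.525 with an estimated correlation. The members that rose numbered 5 without day 4 replicate 1 or 2, and 4 without day 4 replicate 3, control replicate 1 or control replicate 3. Adipocyte markers had only 2 tested members, PPARG at 1.15 and FABP4 at 0.88, and both rose (2 adjusted over the list alone). The list's adjusted p of 0.042 became 0.052 without day 8 replicate 2 and 0.079 without day 8 replicate 3. It was 0.10 with replicates paired and 0.059 with libraries rescaled to equal sums. It was 0.053 by median ratio, 0.10 under quantile normalization and 0.12 with no filter. It was 0.053 with voom, 0.089 in a fit of the compared groups and 0.35 after the GC correction, where FABP4 lost its call (0.45, adjusted p = 0.14), and adjusted p = 0.275 with an estimated correlation.

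Other lists did not pass at day 4. Checkpoint kinases and mediators rose in 1 of 16 and fell in 6 (1 and 6 adjusted over the list alone, adjusted p = 0.51), interferon response genes in 5 and 2 of 25 (4 and 2 adjusted over the list alone, adjusted p = 0.20), hypoxia and glycolysis genes in 10 and 14 of 32 (10 and 15 adjusted over the list alone, adjusted p = 0.63), and unfolded protein response genes in 5 and 13 of 25 (5 and 14 adjusted over the list alone, adjusted p = 0.22, or 0.014 with no filter). Cytosolic ribosomal protein genes rose in 2 of 63 and fell in 2 (0 and 0 adjusted over the list alone, adjusted p = 0.86); without day 8 replicate 3 these counts were 7 and 17, and without day 8 replicate 2 the falls numbered 4. Under quantile normalization 23 of them rose and 4 fell, and the list passed as up (0.0041). Hypoxia and glycolysis genes that rose numbered 6 without day 4 replicate 1 or 2, and interferon response genes that rose 3 without control replicate 1. Without day 8 replicate 3, 9 interferon response genes rose and 5 fell, and 3 checkpoint genes rose. Epithelial markers rose in 1 of 6 and fell in 2 (1 and 3 adjusted over the list alone, adjusted p = 0.43), with keratin KRT7 at -2.35. Endothelial markers rose in 2 of 4 and fell in 0 (2 and 0 adjusted over the list alone, adjusted p = 0.12, or 0.043 once GC content and length were corrected and 0.049 with GC content corrected and replicates paired). Of 2 neural markers, SYP rose by 1.61 and NEFM fell by 2.03 (1 and 1 adjusted over the list alone, adjusted p = 0.95), and of 2 chondrocyte and osteoblast markers, ALPL fell by 1.53 and the other was not called (0 and 1 adjusted over the list alone, adjusted p = 0.53). None of the leukocyte markers reached the filter, and the highest group mean among those in the file was 0.338 FPKM. Median, mean and test differed in sign for the HOX list (median -0.01, mean 0.06) and the matrix list (median -0.03, mean 0.05), both tested as up. With replicates paired, in a fit of control and day 4 alone, 12 ribosomal protein genes rose and 30 fell, and 13 interferon response genes rose and 6 fell. Under the same block 9 NF-kappaB genes rose and 5 fell, and 5 PRC2 genes, 4 HOX genes, 5 epithelial markers and 3 lysosomal genes fell. Rises then numbered 7 for PRC1, 6 for cholesterol biosynthesis, 5 for checkpoint genes and 4 for homologous recombination. After the GC correction of all libraries 4 of 10 PRC2 genes rose and 5 fell. PRC1 genes then rose in 4 of 17 and fell in 9, checkpoint genes rose in 4 and fell in 6, and NF-kappaB genes rose in 9 of 19 and fell in 4. Ribosomal protein genes rose in 3 of 62 and fell in 5, and all 4 endothelial markers rose.

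Over all 11942 genes, limma called 6172 at day 4, of which 2633 rose and 3539 fell; 751 rises and 947 falls were 2-fold or more. The 3 knockdown libraries lay wholly above or below the 3 control libraries for 69.6% of genes, against 10% by chance. Across genes the day 4 change correlated with GC content at a Spearman rho of -0.269, with a median of 0.36 in the lowest quintile of GC content and -0.18 in the highest. Rescaling the libraries to equal sums moved the median change of the genes tested from -0.05 to 0.21 and the share of calls that rose from 42.7% to 62.8%. With the filter and pseudocount unchanged, 15604 genes were then tested against 11942, so the shift need not come from scaling alone. The largest rises after VGF and IL8 were the receptor gene IL13RA2 (4.48), the amino acid transporter SLC6A15 (4.29), the collectin COLEC10 (4.21), the granin SCG2 (3.91), the histone gene HIST2H2BE (3.84) and C11orf96 (3.82). The largest falls were those of the pseudogene PTMAP2 (-3.19), cardiac actin ACTC1 (-3.15), ACTA2, the BMP antagonist GREM1 (-3.07), ACTG2, the transcript RP11-109L13.1 (-3.04), LMOD1 and MCM6 (-3.00). PTMAP2 and HIST2H2BE have near-identical copies elsewhere in the genome, so their reads are uncertain.

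The comparison of day 8 with control asks the same of the later time. At day 8 all 66 G2 and mitosis genes had fallen, and 16 of 18 tested cytokine and chemokine genes had risen (list adjusted p = 6.7e-35 and 1.2e-07). With an estimated correlation neither list passed (adjusted p = 0.0804 and 0.182). CDC20 fell from 139 ± 19.5 to 1.60 ± 0.248 FPKM and LMNB1 from 32.1 ± 1.46 to 0.893 ± 0.0221 (SD, n = 3). IL8 rose from 1.36 ± 0.0641 to 148 ± 49.3, the adhesion receptor ICAM1 from 8.12 ± 0.688 to 175 ± 11.8, and CDKN2B from 0.394 ± 0.0180 to 12.3 ± 1.05. CDKN2A rose from 0.996 ± 0.20 to 4.00 ± 1.27 and IL6 from 1.116 ± 0.283 to 7.72 ± 2.21.

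All 66 G2 and mitosis genes fell at day 8 (66 adjusted over the list alone), with a median log2 change of -3.52. CDC20 fell by 6.05 (SE 0.13), the mitotic kinesin KIF20A by 5.50 (SE 0.12) and the ubiquitin-conjugating enzyme UBE2C by 5.44 (SE 0.14). The list's camera adjusted p was 6.7e-35, and adjusted p = 0.0804 with an estimated correlation. DNA replication and S phase genes fell in 50 of 51 and rose in 0 (50 and 0 adjusted over the list alone), with TK1 at -5.62 (SE 0.21) and the ribonucleotide reductase subunit RRM2 at -5.19 (SE 0.12); the adjusted p was 1.6e-25, and adjusted p = 0.0668 with an estimated correlation. Homologous recombination and Fanconi anaemia genes fell in 22 of 26 and rose in 0 (22 and 0 adjusted over the list alone), with UBE2T at -3.41 and RAD54L at -3.12. Their adjusted p was 1.2e-09, and adjusted p = 0.0804 with an estimated correlation. Nuclear lamina and HMG protein genes fell in 10 of 12 and rose in 1 (10 and 1 adjusted over the list alone), with LMNB1 at -4.55 (SE 0.10, adjusted p = 3.2e-09) and the chromatin protein HMGB2 at -3.80 (SE 0.11). The list's adjusted p was 4.5e-05, and adjusted p = 0.0786 with an estimated correlation.

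CDKN2B rose by 3.84 at day 8 (SE 0.10, adjusted p = 3.6e-09), CDKN1A by 1.64 (SE 0.20, adjusted p = 8.2e-05) and CDKN2A by 1.55 (SE 0.20, adjusted p = 0.00015). CDKN2C fell by 3.89 and CDKN3 by 3.79. Among the 8 CDK inhibitors 4 rose and 3 fell (4 and 3 adjusted over the list alone, list adjusted p = 0.88), and the median of 0.02 and the mean of -0.17 differed in sign. Targets of p53 rose in 28 of 39 and fell in 3 (28 and 3 adjusted over the list alone), with GDF15 at 3.67 (SE 0.18) and the decoy receptor TNFRSF10C at 2.70 (SE 0.09). Camera gave an adjusted p of 1.4e-07, and adjusted p = 0.0668 with an estimated correlation. The falls numbered 5 without day 8 replicate 3, and after the GC correction 32 rose and 5 fell.

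Cytokines and chemokines of the secretory phenotype rose in 16 of 18 and fell in 1 (16 and 1 adjusted over the list alone), with a median of 2.58. Of the list's 36 genes 32 were in the file, and 14 of these stayed below the expression filter. CCL20 and CSF2 reached the filter only through their day 8 libraries, so the share that rose partly reflects the filter. IL8 rose by 6.27 (SE 0.21), CXCL1 by 6.04 (SE 0.20), CCL20 by 4.30 (SE 0.22) and IL6 by 2.33 (SE 0.20, adjusted p = 9.1e-06). The list's adjusted p was 1.2e-07, and adjusted p = 0.182 with an estimated correlation. The NF-kappaB list shares IL8, CXCL1, CXCL2, IL6, CCL2 and ICAM1 with the secretory lists, so these list results are not independent. NF-kappaB pathway genes rose in 14 of 20 and fell in 0 (14 and 0 adjusted over the list alone), with ICAM1 at 4.35 (SE 0.12). Their adjusted p was 7.9e-08, and adjusted p = 0.162 with an estimated correlation. Secreted proteases and growth factors rose in 18 of 36 and fell in 9 (19 and 10 adjusted over the list alone); the insulin-like growth factor carrier IGFBP3 fell by 3.68. As a list they had an adjusted p of 0.012, or 0.062 after a GC correction without day 8 replicate 3, and adjusted p = 0.301 with an estimated correlation. Lysosomal genes rose in 25 of 29 and fell in 1 (25 and 1 adjusted over the list alone), with CTSS at 3.60 and TPP1 at 1.60; the adjusted p was 6.6e-09, and adjusted p = 0.14 with an estimated correlation.

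Fibroblast matrix genes fell in 25 of 42 and rose in 7 (27 and 7 adjusted over the list alone), with the hyaluronan synthase HAS2 at -3.44 (SE 0.21), decorin (DCN) at -2.99 (SE 0.12) and FBN2 at -2.66 (SE 0.17). Over the list the adjusted p was 0.00027, and adjusted p = 0.301 with an estimated correlation. Smooth muscle and myofibroblast markers fell in 11 of 13 and rose in 0 (11 and 0 adjusted over the list alone), with ACTG2 at -4.57 and LMOD1 at -3.77; the adjusted p was 5.8e-06, and adjusted p = 0.14 with an estimated correlation. Developmental regulators that carry H3K27me3 in many cell types fell in 15 of 26 and rose in 5 (16 and 5 adjusted over the list alone), with FOXE1 at -4.39 (SE 0.12) and TBX4 at -3.14 (SE 0.11). Their adjusted p was 0.0057, or 0.29 with no filter, where 97 members were tested, and adjusted p = 0.163 with an estimated correlation. Cholesterol biosynthesis genes rose in 11 of 23 and fell in 1 (11 and 1 adjusted over the list alone), with HMGCS1 at 1.46 and MSMO1 at 1.23; the adjusted p was 0.0063, and adjusted p = 0.227 with an estimated correlation.

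Endothelial markers rose in 3 of 4 and fell in 0 at day 8 (3 and 0 adjusted over the list alone). TIE1 rose by 2.02, and ESAM, which reached the expression filter only through day 8, by 1.53. The adjusted p of 0.040 became 0.26 without day 8 replicate 3, 0.15 without day 8 replicate 1 and 0.095 without day 8 replicate 2, and was adjusted p = 0.163 with an estimated correlation. It was 0.11 with no filter or with libraries rescaled to equal sums, 0.14 with a minimum FPKM of 3 and 0.080 under quantile normalization. Cytosolic ribosomal protein genes fell in 16 of 63 and rose in 0 (2 and 0 adjusted over the list alone), with RPL19 at -1.32. Their adjusted p of 0.012 became 0.13 under quantile normalization and 0.46 without day 8 replicate 3, with the list median at -0.07 against -0.33, and was adjusted p = 0.792 with an estimated correlation. The falls numbered 32 without day 8 replicate 2, 8 without control replicate 2 and 7 without control replicate 3, and the rises 4 without day 8 replicate 3.

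Lists that did not pass at day 8 were PRC2 subunits (2 rose and 4 fell of 11, 2 and 4 adjusted over the list alone, adjusted p = 0.52), PRC1 subunits (4 and 6 of 18, 4 and 7 adjusted over the list alone, adjusted p = 0.73), HOX genes (1 and 5 of 14, 1 and 5 adjusted over the list alone, adjusted p = 0.33) and checkpoint kinases and mediators (1 and 9 of 16, 2 and 9 adjusted over the list alone, adjusted p = 0.11, or 0.017 with no filter). HOXA2 fell by 1.04, PHF19 by 1.58, and the kinase gene CHEK1 fell by 2.25. Checkpoint genes that fell numbered 4 without control replicate 2, and HOX genes that rose 3 without day 8 replicate 3. Interferon response genes rose in 8 and fell in 5 of 25 (8 and 5 adjusted over the list alone, adjusted p = 0.29), hypoxia and glycolysis genes in 6 and 15 of 32 (6 and 16 adjusted over the list alone, adjusted p = 0.35), unfolded protein response genes in 5 and 7 of 25 (5 and 7 adjusted over the list alone, adjusted p = 0.94; 7 and 6 when rescaled to equal sums) and mitochondrial transcripts in 3 and 3 of 13 (2 and 2 adjusted over the list alone, adjusted p = 0.72). Interferon response genes that fell numbered 2 without control replicate 3, and mitochondrial transcripts that fell 1 without control replicate 2, day 4 replicate 1 or 2, or day 8 replicate 1. The glucose transporter SLC2A3 rose by 2.33 and asparagine synthetase ASNS fell by 3.01. Epithelial markers rose in 2 and fell in 2 of 6 (3 and 2 adjusted over the list alone, adjusted p = 0.88), and the neural markers SYP and NEFM changed by 2.73 and -3.82 (1 and 1 adjusted over the list alone, adjusted p = 0.92). PPARG rose by 1.42 as 1 of 2 adipocyte markers (1 adjusted over the list alone, adjusted p = 0.39) and ALPL fell by 2.09 as 1 of 2 chondrocyte and osteoblast markers (1 adjusted over the list alone, adjusted p = 0.52). Median and test differed in sign for the unfolded protein response (-0.05, tested as up) and mitochondrial lists (-0.10, tested as up), and median and mean for the epithelial list (0.10 and -0.09). No leukocyte marker could be tested. After the GC correction PRC1 genes rose in 7 of 17 and fell in 9, HOX genes in 3 and 7 of 14, and hypoxia and glycolysis genes in 10 and 16 of 32. Unfolded protein response genes then rose in 8 and fell in 10, and mitochondrial transcripts in 6 and 3.

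At day 8 limma called 6318 of 11942 genes, of which 2959 rose and 3359 fell; 894 rises and 1251 falls were 2-fold or more. Libraries of the groups did not overlap for 57.2% of genes, against 10% by chance. The Spearman rho of the day 8 change with GC content was 0.0275. Rescaling to equal sums, where 15604 genes passed the filter, moved the median of the genes tested from -0.01 to 0.15. The share of calls that rose moved from 46.8% to 59.1%. Under quantile normalization 3462 rose and 3224 fell. The largest rises beside VGF (6.31), IL8 and CXCL1 were the cystatin CST1 (5.37), HIST2H2BE (5.20), the tight junction gene CLDN1 (5.15), the TNF superfamily ligand TNFSF15 (5.13) and the transporter SLC16A6 (4.84). The largest falls beside CDC20, TK1, KIF20A and UBE2C were those of MYBL2 (-5.39), the mitotic kinase PLK1 (-5.33), RRM2 (-5.19) and KIF2C (-5.03).

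**Figure D3:**
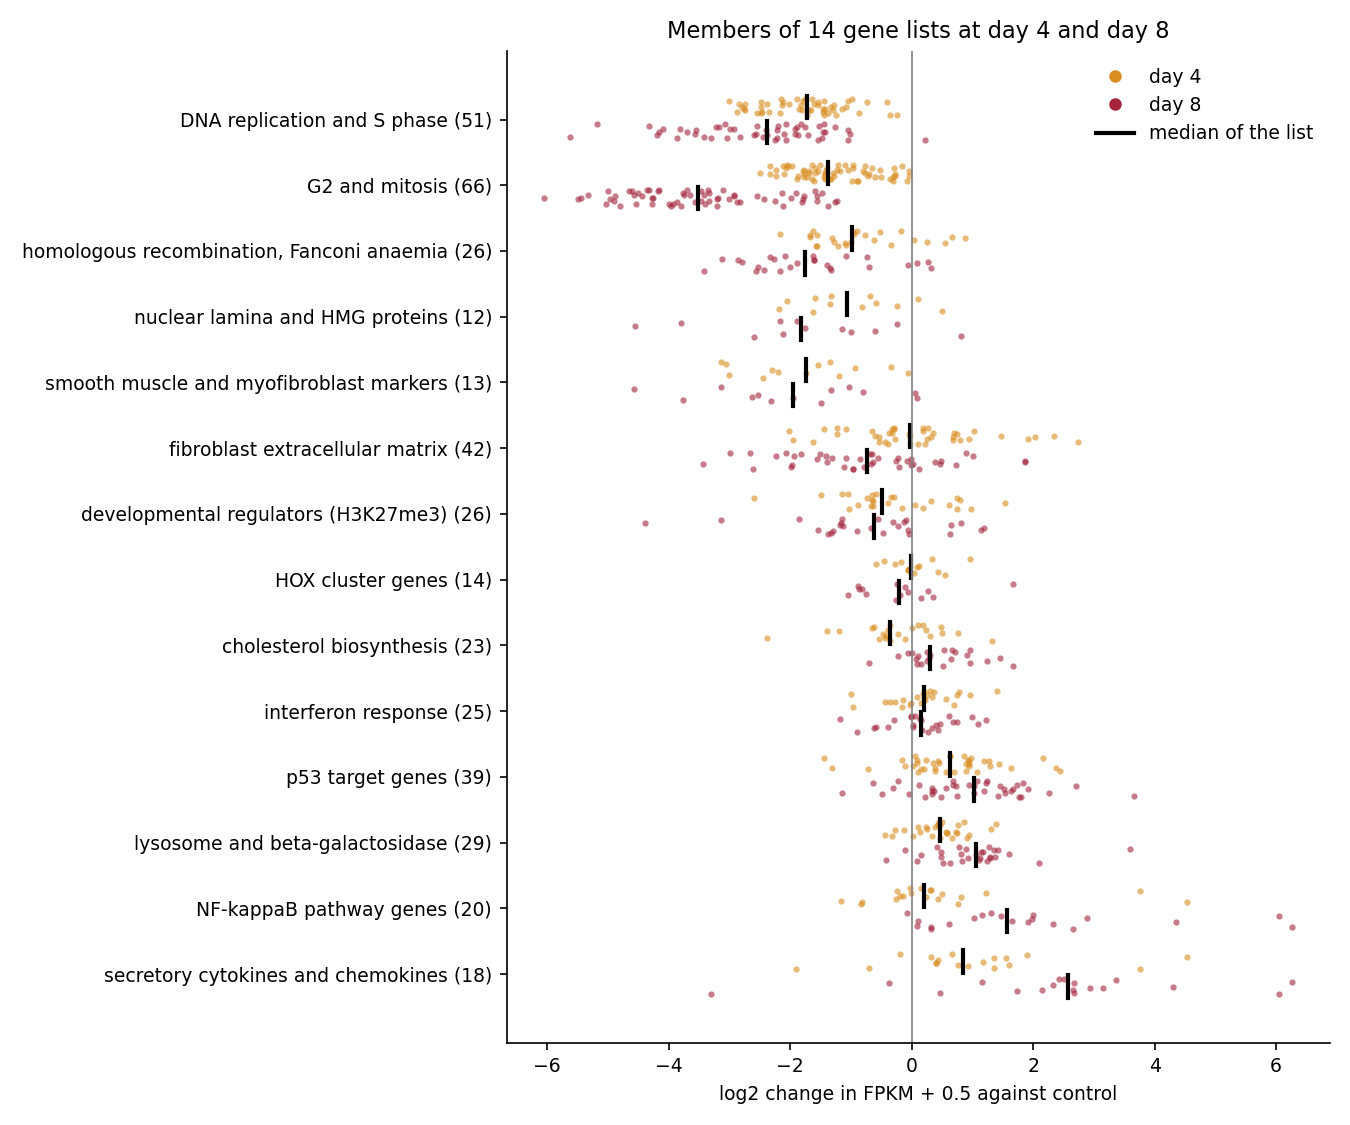
Log2 change in FPKM + 0.5 against control of each tested member (points) of 14 gene lists at day 4 and day 8, with the median of the list (black bar) and the number of members tested in brackets. The G2 and mitosis median moved from -1.37 at day 4 to -3.52 at day 8; the day 4 medians of the matrix and HOX lists change sign when libraries are rescaled to equal sums.

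The comparison of day 8 with day 4 tests whether the changes against the shared controls differed between the times. The controls cancel in it and adjust for nothing, so time in culture is not separated from time after infection. Complement C3 rose from 0.177 ± 0.0576 FPKM at day 4 to 14.1 ± 4.12 at day 8 and ICAM1 from 14.7 ± 1.81 to 175 ± 11.8, while UBE2C fell from 28.5 ± 3.82 to 1.14 ± 0.226 and decorin (DCN) from 131 ± 8.02 to 14 ± 1.44 (SD, n = 3). EZH2 fell further, by 0.71. LMNB1 fell by 2.49 (SE 0.10, adjusted p = 3.6e-07). CDKN1A rose by 0.69, CDKN2A by 1.81, CDKN2B by 1.88 and IL6 by 1.89 between the times.

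All 66 G2 and mitosis genes fell from day 4 to day 8 (66 adjusted over the list alone), with UBE2C at -4.15 (SE 0.14) and CDC20 at -3.56 (SE 0.13); the list's adjusted p was 1.9e-51, and adjusted p = 0.0671 with an estimated correlation. DNA replication genes fell in 40 of 51 and rose in 1 (43 and 1 adjusted over the list alone), with RRM2 at -3.04. Their list adjusted p was 7.2e-17, and adjusted p = 0.0671 with an estimated correlation; without day 8 replicate 3, 3 of them rose. Homologous recombination and Fanconi anaemia genes fell in 19 of 26 and rose in 0 (21 and 0 adjusted over the list alone), at 1.7e-11 and adjusted p = 0.0671 with an estimated correlation. Lamina and HMG protein genes fell in 6 of 12 (6 adjusted over the list alone), with HMGB2 at -2.20, at 0.00036 and adjusted p = 0.0671 with an estimated correlation. Fibroblast matrix genes fell in 25 of 42 and rose in 2 (27 and 2 adjusted over the list alone), with DCN at -3.19 (SE 0.12) and HAS2 at -3.16 (SE 0.21), at 4.4e-10 and adjusted p = 0.116 with an estimated correlation. Developmental regulators fell in 14 of 26 and rose in 1 (14 and 2 adjusted over the list alone), with FOXE1 at -1.80, at 2.8e-05, or 0.34 with no filter, and adjusted p = 0.0671 with an estimated correlation.

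NF-kappaB pathway genes rose in 18 of 20 and fell in 0 (18 and 0 adjusted over the list alone), with ICAM1 at 3.53 (SE 0.12) and CXCL1 at 2.28 (SE 0.20); the list's adjusted p was 4.9e-12, and adjusted p = 0.0758 with an estimated correlation. Cytokines and chemokines rose in 15 of 18 and fell in 2 (15 and 2 adjusted over the list alone), with CCL20 at 3.13 (SE 0.22) and CSF2 at 2.75 (SE 0.18), at 3.0e-07 and adjusted p = 0.201 with an estimated correlation. CCL20 and CSF2 reached the expression filter only through day 8. Cholesterol biosynthesis genes rose in 17 of 23 and fell in 0 (18 and 0 adjusted over the list alone), with DHCR7 at 1.40 (SE 0.13), at 2.9e-07 and adjusted p = 0.0671 with an estimated correlation. These rises numbered 11 without day 4 replicate 1 or day 8 replicate 1, and falls 2 without day 8 replicate 3. Lysosomal genes rose in 18 of 29 and fell in 1 (21 and 1 adjusted over the list alone), with CTSS at 2.21 and the autophagy receptor SQSTM1 at 1.33, at 2.0e-06 and adjusted p = 0.193 with an estimated correlation. Targets of p53 rose in 17 of 39 and fell in 1 (17 and 1 adjusted over the list alone), with TNFRSF10C at 1.51, at 0.00052 and adjusted p = 0.0766 with an estimated correlation. These rises numbered 11 without day 4 replicate 1, day 4 replicate 2 or day 8 replicate 1, and the falls 7 without day 8 replicate 3. After the GC correction 26 rose and 1 fell.

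Calls of the ribosomal and HOX lists were lost without day 8 replicate 3. Cytosolic ribosomal protein genes fell in 4 of 63 (0 adjusted over the list alone) and the list passed at 0.00086, against 0.74 without that library and adjusted p = 0.702 with an estimated correlation. The falls numbered 9 without day 8 replicate 2, 2 without day 4 replicate 3 or day 8 replicate 1, 1 without day 4 replicate 1 and 0 without day 4 replicate 2, and the rises 3 without day 8 replicate 3. The falls were 16 of 62 after the GC correction (adjusted p = 0.00017), 21 with libraries rescaled to equal sums, 13 by median ratio and 37 under quantile normalization. HOX genes rose in 1 of 14 and fell in 6 (1 and 6 adjusted over the list alone), with HOXA2 at -0.99, at 0.027, against 0.32 without that library, 0.49 with no filter, 0.082 with libraries rescaled to equal sums and adjusted p = 0.521 with an estimated correlation. Unfolded protein response genes rose in 9 of 25 and fell in 1 (9 and 1 adjusted over the list alone), with SDF2L1 at 0.79, at 0.027, against 0.21 under quantile normalization, 0.056 with a minimum FPKM of 3 and adjusted p = 0.444 with an estimated correlation. Their rises numbered 16 and their falls 3 without day 8 replicate 3.

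Lists that did not pass between the times were mitochondrial transcripts (2 rose and 7 fell of 13, 2 and 7 adjusted over the list alone, adjusted p = 0.054), endothelial markers (3 and 1 of 4, 3 and 1 adjusted over the list alone, adjusted p = 0.12), epithelial markers (3 and 0 of 6, 3 and 0 adjusted over the list alone, adjusted p = 0.11) and smooth muscle and myofibroblast markers (2 and 4 of 13, 2 and 4 adjusted over the list alone, adjusted p = 0.42). The mitochondrial list passed without control replicate 1 (0.043), control replicate 2 (0.034), control replicate 3 (0.043), day 4 replicate 1 (0.039), day 4 replicate 2 (0.042) or day 8 replicate 2 (0.035), with libraries rescaled by median ratio (0.034) or to equal sums (0.045), with a pseudocount of 1 (0.040), with no filter (0.0096) or a minimum FPKM of 3 (0.025), with the replicate block (0.044) and in a fit of the compared groups (0.043), and the epithelial list without day 8 replicate 3 (0.048). Mitochondrial transcripts that fell numbered 3 without day 4 replicate 1, day 4 replicate 2 or day 8 replicate 1 and 4 without day 4 replicate 3, and endothelial markers that rose numbered 1 without day 8 replicate 1 or 2. Smooth muscle markers that rose numbered 4 without day 8 replicate 3. MT-ND6 rose by 0.88, ESAM by 1.42 and CLDN7 by 1.09, and NEFM fell by 1.80. Proteases and growth factors rose in 10 and fell in 10 of 36 (11 and 11 adjusted over the list alone, adjusted p = 0.73), with ANGPT1 at -2.38; their median of -0.00 and mean of 0.05 differed in sign. PRC2 subunits rose in 1 and fell in 3 of 11 (1 and 4 adjusted over the list alone, adjusted p = 0.11, or 0.012 with a minimum FPKM of 3), PRC1 subunits in 3 and 3 of 18 (3 and 3 adjusted over the list alone, adjusted p = 0.62), CDK inhibitors in 3 and 3 of 8 (3 and 3 adjusted over the list alone, adjusted p = 0.66) and checkpoint genes in 2 and 5 of 16 (2 and 5 adjusted over the list alone, adjusted p = 0.14), with CHEK1 at -1.21. Without day 8 replicate 3, 5 PRC1 genes rose and 8 fell, 4 checkpoint genes rose and 8 fell, 7 interferon response genes rose and 9 fell, and 7 PRC2 genes fell. PRC1 falls numbered 1 without any other library except day 4 replicate 3, and PRC1 rises 1 without day 4 replicate 1 or 2 or day 8 replicate 1. Checkpoint rises numbered 0 without control replicate 1 or 2, any 1 of the day 4 libraries or day 8 replicate 1. Interferon response falls numbered 1 without control replicate 1 or 2, any 1 of the day 4 libraries or day 8 replicate 1, PRC2 falls 1 without control replicate 2, and hypoxia and glycolysis falls 2 without day 4 replicate 1 or 2 or day 8 replicate 1. Interferon response genes rose in 3 and fell in 3 of 25 (3 and 2 adjusted over the list alone, adjusted p = 0.91) and hypoxia and glycolysis genes in 6 and 4 of 32 (6 and 4 adjusted over the list alone, adjusted p = 0.62), with CA9 at -1.33. Falls of the hypoxia list outnumbered its rises after the GC correction (5 rose and 13 fell, adjusted p = 0.11), under quantile normalization (5 and 12), by median ratio (6 and 8), with equal sums (5 and 7) and with library weights (12 and 14). After the GC correction PRC1 genes rose in 2 of 17 and fell in 5, interferon response genes in 4 and 5 of 25, and proteases and growth factors in 11 and 14 of 36. Mitochondrial transcripts then rose in 2 and fell in 4, and epithelial markers in 3 and 2. SYP rose and NEFM fell among neural markers (1 and 1 adjusted over the list alone, adjusted p = 0.66), FABP4 fell by 1.01 among adipocyte markers, a call lost after the GC correction, where 1 rose and 0 fell (1 rose and 1 fell adjusted over the list alone, adjusted p = 0.61), and ALPL fell by 0.56 among chondrocyte and osteoblast markers, a call lost under quantile normalization (0 and 1 adjusted over the list alone, adjusted p = 0.52).

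Between the times limma called 3815 genes, of which 2159 rose and 1656 fell; 244 rises and 464 falls were 2-fold or more, and libraries did not overlap for 41.2% of genes, against 10% by chance. The largest rises were C3 (4.39), the cytochrome CYP1A1 (3.55), ICAM1 (3.53), CLDN1 (3.47) and TNFSF15 (3.37), and the largest falls UBE2C, CDC20, KIF20A (-3.40), KIF2C (-3.39) and the cytokinesis gene ANLN (-3.26). The count depended on single libraries: it was 2115 without day 4 replicate 1, 2180 without day 4 replicate 2, 2112 without day 8 replicate 1 and 7377 without day 8 replicate 3. Falls outnumbered rises without day 8 replicate 1 (1036 rose and 1076 fell), without day 8 replicate 2 (1284 and 1341) and when libraries were rescaled by median ratio (1795 and 1947). Rescaling to equal sums, where 15604 genes passed the filter, moved the median of the genes tested from 0.03 to -0.07. Across genes the change correlated with GC content at a Spearman rho of 0.461, with a median of -0.35 in the lowest quintile of GC content and 0.26 in the highest.

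The changes at both times were compared gene by gene. Rises at both times were shared by 1775 genes and falls by 2565, where independent lists would share 652 and 995. Another 50 genes rose at day 4 and fell at day 8, and 52 fell and then rose. Fold changes correlated at r = 0.797 across genes, against 0.498 for simulated unchanged groups measured against the same controls (mean of 50 simulations). Their covariance was 0.542 against a simulated 0.0191, and in the simulations 0 genes were called in both comparisons. No simulated gene was changed, so that 0 follows from the setting and says nothing about the shared calls. The simulated noise was also independent between genes and lacked the trends with GC content seen in the libraries. The simulated correlation and covariance may therefore be too low a baseline. The 3 control libraries were not split, since each side would need at least 2. Part of the excess over independent lists may come from sharing them. On the set tests, 11, 15 and 14 of 28 lists passed camera with the preset correlation at day 4, at day 8 and between the times, and 0 in each with an estimated correlation. At an unadjusted p under 0.05 that estimate gave 5, 8 and 9 lists. Limma's fry, which does not compare a list with other genes, called 24, 24 and 23.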

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

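The tests of day 8 replicate 3 and of GC content below were chosen after the results they bear on had been seen; the differences between the times and the splits of the libraries were planned. Each result here stands out because the change against the shared controls at day 8 differed from that at day 4 by a test of the difference itself. That held for 3815 genes. Of these, 102 were past the threshold at both times in opposite directions. Among them, chosen after their values were seen, the glycoprotein hormone subunit CGA changed by 1.49 at day 4 and by -1.75 at day 8, the protease inhibitor LXN by 0.94 and -1.43, and the pregnancy-specific glycoprotein PSG2 by -0.29 and 2.66. PSG genes are near-identical copies of each other, so their reads are uncertain.

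EZH2 differed by -0.71 between the times, LMNB1 by -2.49, CDKN1A by 0.69, CDKN2A by 1.81, CDKN2B by 1.88 and IL6 by 1.89 on the log2 scale. In the list test 14 gene lists differed between the times, and 0 with an estimated correlation (lowest adjusted p = 0.0671; 9 lists at an unadjusted p under 0.05). Cholesterol biosynthesis genes had a median difference of 0.68 (camera adjusted p = 2.9e-07, and adjusted p = 0.0671 with an estimated correlation).

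The other splits of the libraries are too few for a share under 0.05. In each comparison 1 of the 10 splits of 6 libraries, the real one, gave as many genes. The real splits called 6172, 6318 and 3815 genes, and the highest of the other splits called 0 in each. Every other split mixes libraries of both groups, so a real difference between the groups widens the spread within it. Few calls were therefore bound to follow, and the 0 does not measure noise or argue against chance. At day 4 against control, where the replicate numbers may pair the libraries, the real split parts all 3 such pairs. The 3 other splits that do so and the 6 that part fewer called 0.

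Day 8 replicate 3 lay apart from the other day 8 libraries, with a deviation SD of 0.363 on the log2 scale against 0.121 to 0.272 in the other libraries and 26343204 reads, and without it 7377 genes differed between the times; it correlated with the day 4 libraries at r = 0.952, 0.948 and 0.951, about as with day 8 replicate 2 (0.951). A day 4 library under a day 8 label would hold mitosis genes at their day 4 level and lie nearer day 4, but over 1067 genes that separate the times its median position was 0.628 of the way from day 4 to the other day 8 libraries (95% bootstrap interval 0.592 to 0.649). RNA from day 4 cells as the whole cause would shift all such genes by a like share, but the level of 61 G2 and mitosis genes, which argues against a whole day 4 library too, needed 2.21% of day 4 RNA (0.948 to 3.06) against 36.7% (33.3 to 42.8) for all 1067. The needed share also followed GC content, at 75% (66.2 to 83.4) in the lowest quintile and 4.51% (1.5 to 11.1) in the middle one. All these intervals resampled genes, which are not independent, and do not measure the spread between libraries. A small share of day 4 RNA beside another cause stays open. A bias with GC content may account for part of its distance and stays open: a spline on GC content took away 45.1% of the variance of its deviation, or 54.7% with gene length, on either side of the 50% set for such a bias after the data were seen, and no biological explanation was tested.

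Genes that differed between the times followed GC content, so that a GC bias could have produced the calls. Of 3752 called genes with a known GC content, 3280 kept their direction and threshold after the correction, which is 87.4% (95% interval 86.3 to 88.5). The interval treats genes as independent and does not measure the spread between libraries. The correction also raised all calls between the times from 3815 to 4856, which makes a call easier to keep. A corrected fit without day 8 replicate 3 kept 3184 of the main calls and reversed 16. The calls kept argue against GC content as the whole cause. In the lowest quintile of GC content 425 of 598 were kept, so for genes that lost the call a GC bias stays open. The time after knockdown, which the labels name, stays open as a biological explanation and cannot be told apart from time in culture.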

How the results depend on the processing

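The alternatives with a GC correction, voom on recovered reads and the block on control and day 4 alone were added after seeing the data; the others were planned. Over all alternatives, the changes of named genes kept their direction and their side of the threshold 5969 times. They lost the call 68 times, gained it 9 times and reversed 0 times. Apart from the genes fixed in advance, named genes were picked as called in these same data and ranked by size of change. Keeping the call is thus partly built in, and the tally does not describe genes in general. List tests kept their side of the threshold 2118 times, lost it 75 times, gained it 19 times and reversed once, for the cytosolic ribosomal proteins at day 4 under quantile normalization (adjusted p = 0.0041, against 0.855). Counts of genes or lists called stayed within 1.5 times in 153 cases, rose past that in 10 and fell past it in 11. Counts of list members did so in 3932, 218 and 108. EZH2 between the times lost its call under quantile normalization (-0.24). Library weights, whose estimation warned of incomplete convergence, raised the calls to 10099 at day 8 and 10020 between the times. A fit of only the compared groups gave 2529 between the times. Leaving out 1 library at a time gave 2112 to 7377 between the times, lowest without day 8 replicate 1 and highest without day 8 replicate 3; the GC correction without day 8 replicate 3 gave 6910. Apart from leaving out libraries, which changes their number, the cause was not tested. A 2-fold minimum left 1698, 2145 and 708 genes by construction. An adjusted p under 0.01 left 1151 genes that rose at both times. With an estimated correlation camera passed 0 lists at day 4, 0 at day 8 and 0 between the times; fry passed 24, 24 and 23 by direction and 24, 25 and 24 as mixed sets. Voom on recovered reads called 6149, 6320 and 3843 genes, of which 6058, 6229 and 3708 were among the main calls.

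Replicate numbers may pair control with day 4, which these data do not settle. Same-number pairs with day 8 correlated above 0.1 in 0 of 3 with control and 1 of 3 with day 4. Day 8 replicate 3 followed GC content in the opposite direction (Spearman -0.657) to control and day 4 replicates 3 (0.652 and 0.727). Such trends could hide a pairing, so pairing with day 8 is not excluded. Of 9 pairs with the same number, 4 had correlated deviations above 0.1, with a range from -0.519 to 0.44. Only 1 library correlated best with its own number. With the replicate block over all libraries 5436, 5753 and 2692 genes were called. In a fit of control and day 4 alone the block called 9141 genes, or 8909 with the GC correction, against 7912 in a fit of these groups with no block. Among named genes and lists it changed the calls of IL6 and the adipocyte list, and with the GC correction also that of the endothelial list, and no other. The first 2 also changed in the fit of these groups with no block. Depth limits what a low value can show: EZH2 at day 8 rests on 16 to 31 reads. Simulated 1.5-fold changes over genes of all levels were called in 29.4% at day 4, where far fewer genes changed than were called in the data.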

Other observations

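All gene groups here were chosen after seeing the data, as was everything tested on them except the planned limma calls. Adjustment over the 21 list tests does not account for that choice, so the list p-values here are descriptive only. The test of small RNAs was set after single histone genes had been seen to rise. Genes of serine and one-carbon synthesis, 9 of enzymes and 2 of amino acid transporters, fell in 11 of 11 at day 4 (median -1.17, adjusted p = 7.9e-07 over 21 such list tests) and in 11 of 11 at day 8 (median -1.86, adjusted p = 2.9e-07), with adjusted p = 0.0896 with an estimated correlation at both times. PHGDH, the first enzyme of the pathway from glycolysis to serine, had a mean of 73.8 FPKM in control, 11.3 at day 4 and 3.99 at day 8. PSAT1, which follows it, had 74.7, 11.5 and 4.42. Genes of the actin cytoskeleton and focal adhesions fell in 21 of 23 at day 4 (median -1.54, adjusted p = 3.1e-10, and adjusted p = 0.0827 with an estimated correlation). At day 8, 21 fell and 1 rose (median -1.27, adjusted p = 2.5e-08, and adjusted p = 0.0896 with an estimated correlation). The actin crosslinkers ACTN4 and ACTN1 changed by -2.79 and -2.87 at day 4 and by -3.09 and -2.62 at day 8.

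Basement membrane collagen IV chains went in opposite directions: COL4A5 rose from 3.54 FPKM in control to 30.5 at day 4 and 38.3 at day 8, and COL4A6 from 0.813 to 8.23 and 16, while COL4A1 fell from 260 to 63.7 and 67.8. The list had 2 rises and 2 falls at each time and did not pass (adjusted p = 0.46 and 0.57). Pregnancy-specific glycoproteins rose in 3 of 3 at day 8 (median 2.66, adjusted p = 0.0031, and adjusted p = 0.129 with an estimated correlation), after 2 of 3 had fallen at day 4. Near-identical copies make these values uncertain.

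In these libraries of polyadenylated RNA, replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, rose while DNA replication genes fell. Histone transcripts without poly(A) tails, and so total histone RNA, were not measured by design. Of 29 tested loci, 5 of them annotated as pseudogenes, 21 rose and 1 fell at day 4 (median 1.28, adjusted p = 1.6e-10) and 25 rose and 0 fell at day 8 (median 2.26, adjusted p = 7.2e-12), with adjusted p = 0.0827 with an estimated correlation at both times. Without the pseudogenes 18 of 24 rose and 1 fell at day 4 (median 1.55), and 22 rose and 0 fell at day 8 (median 2.56), though 10 of the 24 had no annotated gene type. HIST1H1C had a mean of 12.1 FPKM in control, 78 at day 4 and 137 at day 8, and HIST1H2BK 31.8, 80.4 and 181.

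Carry-over of RNA without poly(A) tails might raise small RNAs of that kind as well. The histone median at day 8 lay 2.64 above that of 78 such RNAs (95% bootstrap interval 1.89 to 3.36). Their median was -0.38, with 5 called as rising and 11 as falling. Without the pseudogenes the histone median lay 2.95 above (2.16 to 3.66). Histone loci may share reads and are not independent draws. Small RNAs need not be carried over as histone transcripts are, so this comparison cannot decide and carry-over stays open. A GC bias as the cause is argued against by the GC correction. It was run over the 28 histone loci with a GC value, 9 of them matched by older symbols after a first test on 19. It moved the day 8 median from 2.23 to 2.20, a fall of 1.43% (95% bootstrap interval -3.04 to 3.42). There 24 rises became 23, and 1 locus was called as falling. Without the pseudogenes the median fell by 1.82% (-3.04 to 3.42). Reads shared between histone copies were not tested and stay open, and no biological explanation was tested.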
